A study of Mus musculus with 4 samples.

How the data were processed

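RNA was sequenced from mouse (C57BL/6) splenic naive CD4+ T cells cultured under the Th0 condition without dopamine (Th0) or with dopamine (Th0+Dopa) and harvested on day 4. Each group holds 2 libraries, numbered 2 and 3 in the labels. Th0 is the usual name for activation without the cytokines that steer T helper cells to a lineage. The dose and timing of dopamine are not given in the sources used here. Per the labels' protocols, total RNA was column purified with DNase treatment, and libraries were made with a stranded total RNA kit that depletes ribosomal RNA and globin mRNA. Such libraries hold non-polyadenylated RNA beside mRNA. Sequencing was paired-end on a HiSeq2500, each sample on 2 lanes.

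The deposited values are FPKM (fragments per kilobase of transcript, relative to the mapped fragments of the library) in 2 tables made separately. The first table holds the libraries numbered 2 and the second those numbered 3. The submitters' processing notes name bcl2fastq 1.8.4, Trimmomatic 0.35, FastQC 0.10.1, STAR 2.4.2, Cufflinks 2.2.1 and the mm10 build. The annotation release, the normalization options and the use of strand in counting are not given in the sources used here, so antisense and overlapping genes are uncertain. Each table lists 38282 Ensembl gene IDs in the same order. GENCODE M21 on GRCm38 (the mm10 build) named 36423 of them. The other 1859, of which 134 were tested, are shown by their IDs. Coordinates, GC content and transcript length come from GENCODE M21, the last 2 as means over a gene's transcripts, and 11284 tested genes (98.8%) had them.

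Read counts were not used here. The low values of genes with a single transcript fell near whole multiples of 1 fragment, which gave an estimate of depth. A fragment on a 1 kb transcript was worth 0.152 FPKM in Th0 2, 0.156 in Th0+Dopa 2, 0.203 in Th0 3 and 0.154 in Th0+Dopa 3. Between 84% and 87.8% of these values lay within 0.15 fragment of a whole number, against 30% by chance. By this estimate depth was lowest in Th0 3, and values under about 1 FPKM rest on few fragments. The normalization options are not given, however, and scaling would also move the value of 1 fragment. Th0 3 had the most genes above 0 of the libraries (19177), so its lower depth is uncertain. An exact 0 is written as listed at 0. In all, 273 tested genes, 27 of them protein coding, were listed at 0 in at least 1 library.

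Genes with a mean FPKM of at least 1 over the 4 libraries were tested, 11423 in all, of which 10153 were protein coding. Because the tables were made separately, differences were tested only within a table. The test was limma 3.58.1 (lmFit, then eBayes with trend) in R 4.3.3 on log2(FPKM + 1), with the table, equal to the replicate number, as a block. It was two-sided with Benjamini-Hochberg adjustment, and an adjusted p under 0.05 was a call. The estimate is the mean of the 2 within-table log2 differences, Th0+Dopa minus Th0, given with its standard error (SE) after ±. A fold change on the log2(FPKM + 1) scale understates the change of low genes. The model leaves 1 residual degree of freedom per gene, and the prior fitted over all genes adds 4.70. The block stands for the separately made tables; nothing in the labels says that a number marks a shared animal or culture. Nothing in the labels says that the libraries came from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical.

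Before the data were examined, 36 gene lists were fixed: T helper programs, interferon and STAT signalling, catecholamine handling, activation, cell cycle, metabolism, stress and markers of other cell types. The 33 lists with at least 4 tested genes were compared with all other tested genes by limma's camera (preset inter-gene correlation 0.01, two-sided, adjusted over the 33 lists). For each list the calls over all tested genes and those adjusted over the list alone are given. Named genes follow a rule fixed at the same time. It takes the 10 highest and 10 lowest calls with the same sign in both pairs, leaving out genes with small RNA, Gm or Rik names. It adds genes chosen in advance, among them Il4, Il5, Il13, Gata3, Tbx21, Ifng, Foxp3, Il2ra, Stat2 and Drd4, and up to 4 members of each list. Further list members and other genes were named after their values were seen.

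Alternatives were other pseudocounts, filters, scalings and limma settings, no block, each library left out, camera with an estimated correlation, fry, and 10000 random lists matched on expression. A correction of each pair's differences for GC content and length (loess, span 0.3) was added after the data were seen. Fits that left out a library had no block and used libraries scaled by the median of ratios over all 4. In them, lone libraries of a group were assumed to vary like the others. On simulated data for this comparison (11423 genes, 200 changed, 20 runs), limma recovered 35% of 2-fold and 74.2% of 4-fold changes, and 8.77% of its calls were false, above the nominal 5%. The data themselves gave 1218 calls, many more than the 200 genes changed here. The adjustment depends on how many genes change, so these shares may differ for the data. A list of 25 genes raised 1.5-fold was called in 20 of 20 runs, and 0 of 600 unchanged lists were. Noise was drawn independently for each gene, so these runs do not show how often lists of genes that move together are called falsely. Tables were joined in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9.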

Results

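The data collected were FPKM values for 38282 mouse genes in 4 libraries of cultured splenic CD4+ T cells, 2 from Th0 cultures and 2 from Th0 cultures with dopamine. The study concerns dopamine-releasing nerves and type 2 inflammation of the young lung, and the comparison asks which transcripts differ when CD4+ T cells are activated with dopamine present. FPKM summed to 687066 in Th0 2, 880583 in Th0+Dopa 2, 715110 in Th0 3 and 794873 in Th0+Dopa 3. Genes above 0 numbered 17833, 15974, 19177 and 16276 in the same order. The composition of the libraries moved with the treatment. Mitochondrial genes took 5.64% and 8.41% of the summed FPKM in the Th0 libraries (2 and 3) and 1.55% and 3.35% with dopamine. Mitochondrial ribosomal RNA, which the kit depletes, made up 3.43% and 5.52% in Th0 and 0.473% and 2.01% with dopamine. Mitochondrial coding genes made up 2.21% and 2.90% against 1.08% and 1.34%. Histone cluster genes took 1.14% and 0.978% in Th0 and 2.98% and 2.27% with dopamine, and small RNA genes 16.0% and 14.6% against 21.9% and 17.2%.

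Of 33 tested gene lists, 4 rose and 6 fell with dopamine by camera at its preset correlation. By camera with an estimated correlation 0 passed (adjusted p = 0.703 to 0.831 for these 10). By fry, which tests whether a list's genes move one way on balance, 0 of these 10 passed (adjusted p = 0.0950 to 0.237). The test with an estimated correlation uses 1 residual degree of freedom, so hardly any list could pass it. Its values here and below therefore decide little. The glycolysis list had a camera adjusted p of 0.703 in it although its estimated correlation was -0.048. The higher lists were Th2 genes (9 of 21 members called higher), sterol synthesis (9 of 24), the amino acid and integrated stress response (13 of 25) and nuclear oxidative phosphorylation (12 of 30). The lower lists were glycolysis (14 of 21 called lower), hypoxia (12 of 16), granulocyte and mast cell markers (8 of 9), macrophage and dendritic cell markers (9 of 12), naive and memory T cell genes (4 of 15) and p53 targets (5 of 20). In limma, 717 genes rose and 501 fell among 11423 tested. All 1218 had the same sign in both pairs, but the test with its block lets no gene with opposite signs pass. At an unadjusted p under 0.05 there were 3177. Without a test, 234 genes were at least 2-fold higher in both pairs and 285 at least 2-fold lower, while 29 moved that far in opposite directions. Across genes, which are not independent replicates, the differences of the pairs correlated at Pearson's r = 0.536 and Spearman's rho = 0.551, and at r = 0.705 over protein-coding genes. Without the block, 256 genes were called higher and 240 lower, and in fits that also left out a library there were 20 higher and 23 lower without Th0 2, 2 and 1 without Th0+Dopa 2, 8 and 13 without Th0 3, and 8 and 1 without Th0+Dopa 3. The share of calls that were higher was 58.9% for FPKM as deposited, 26.0% with each library scaled to a common sum (380 higher, 1082 lower) and 31.8% with small RNA genes left out first. The median difference of all genes was -0.21 and -0.14 under these scalings, against 0.03 as deposited. Of the 94 calls that the rule for named genes gave, 40 passed without limma's trend, 68 without the block, 81 with libraries scaled to a common sum, and 9, 0, 4 and 1 in these 4 fits that each left out a library, and none changed sign. The 13 lost with the common sum, which shifts nearly all genes down alike, were all higher as deposited, among them Cd3d, Cdt1, Fdft1, Pdia6, Pim1, Sdhb, Srebf2, Tbx21, Tk1 and Zap70.

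**Figure D1:**
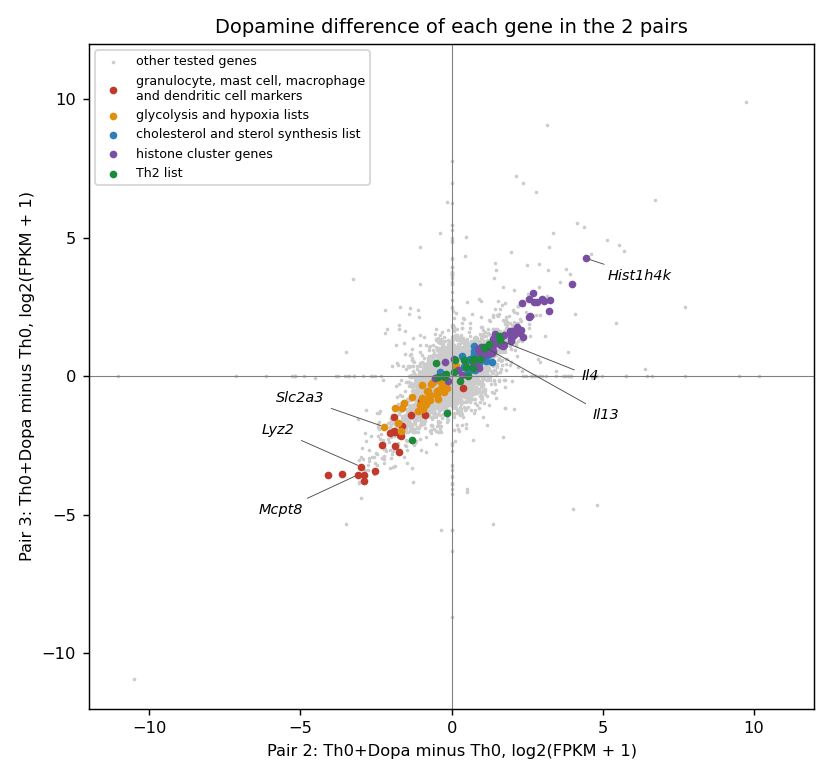
Each point is 1 of 11423 tested genes, with the log2(FPKM + 1) difference Th0+Dopa minus Th0 of pair 2 on the x axis and of pair 3 on the y axis. Coloured points are members of gene groups, and 69.9% of all tested genes have the same sign in both pairs.

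With genes left out that carry small RNA, Gm or Rik names, the 10 genes with the largest rises included 4 histone cluster genes, 3 of them protein coding and 1, Hist1h2al, annotated as a processed pseudogene. Hist1h4k (chromosome 13, 21750194 to 21750505) rose by 4.35 ± 0.11 (limma adjusted p = 9.35e-05), Hist1h2af by 3.66 ± 0.18, Hist1h2al by 3.01 ± 0.14 and Hist1h4j by 2.89 ± 0.11. After the GC and length correction these rises were 3.41 ± 0.10, 2.56 ± 0.11, 1.85 ± 0.09 and 2.79 ± 0.09 in the same order. The others were CAAA01147332.1 at 5.10 ± 0.30, Scand1 at 3.01 ± 0.22, the parathyroid hormone gene Pth at 3.06 ± 0.25, and 3 IDs without a name, whose gene type is not given in the sources used here, so that small RNA is not ruled out, among them ENSMUSG00000045999 at 3.83 ± 0.11 and ENSMUSG00000069312 at 3.51 ± 0.18. After the correction Scand1 had 2.06 ± 0.18 and Pth 3.21 ± 0.25. CAAA01147332.1 was listed at 0 in Th0 2 and Pth in Th0 3. Histone cluster genes are near-identical copies, so the value of any single copy is uncertain. Histone cluster genes were also tested as a group chosen after their values were seen. Of 55 tested, 46 rose and 0 fell, with a median of 1.44 (camera adjusted p = 2.77e-33, or adjusted p = 0.237 with an estimated correlation). Of 184 tested small nuclear, nucleolar and Cajal body RNA genes, also chosen afterwards, 62 rose and 3 fell (camera adjusted p = 4.47e-11, or adjusted p = 0.202 with an estimated correlation).

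With the same genes left out, the 10 genes with the largest falls were all known from granulocytes, mast cells or macrophages. S100a9 and S100a8, the subunits of calprotectin, fell by 3.84 and 3.34 on the log2 scale. Mpo (myeloperoxidase) changed by -3.58 ± 0.19, the basophil protease Mcpt8 by -3.32 ± 0.15, the mast cell carboxypeptidase Cpa3 by -3.22 ± 0.19 and the lysozyme gene Lyz2 by -3.13 ± 0.12. Prss34 (-3.12), Clec7a (-3.05), the Fc receptor chain Fcer1g (-3.03) and the macrophage elastase Mmp12 (-2.99) completed the group, and limma adjusted p was at most 0.00243 for these 10. Mcpt8 (chromosome 14, 56082166 to 56085273) stood at 142 and 187 FPKM in the Th0 libraries and at 15.8 and 15.03 with dopamine. The list of granulocyte and mast cell markers fell (median -3.22, camera adjusted p = 6.72e-12; adjusted p = 0.703 with an estimated correlation): 8 of 9 tested members fell, all 9 when adjusted over the list alone. Macrophage and dendritic cell markers fell too (median -1.92, camera adjusted p = 3.89e-09; adjusted p = 0.703 with an estimated correlation), with 9 of 12 called and 11 adjusted over the list alone. Cd68, a lysosomal protein of macrophages, changed by -2.04 ± 0.24, the transcription factor Spi1 by -1.95 ± 0.25 and Mpeg1 by -1.94 ± 0.26. Cst3, the exception, is a cystatin made by many cell types and had a difference of -0.02 ± 0.20 (adjusted p = 0.957). Of 7 tested B cell markers, the class II genes H2-Aa (-1.55 ± 0.14) and H2-Ab1 (-1.53 ± 0.14) fell, which dendritic cells and macrophages also express; the list did not pass (median -0.08, camera adjusted p = 0.121). T cell identity genes did not pass as a list (median 0.23, camera adjusted p = 0.118). Among its 19 members, Cd5, Cd6, Cd3d and Zap70 rose by 0.96, 0.84, 0.48 ± 0.10 and 0.46 ± 0.10, and Trac, the constant region of the T cell receptor alpha chain, fell (-0.70). After the GC and length correction, Cd3d and Zap70 no longer passed (0.39 ± 0.09 and 0.17 ± 0.09, adjusted p = 0.0646 and 0.319). The CD8 T cell, NK and innate lymphoid, and erythroid lists had fewer than 4 tested genes and were not tested. Without Th0 2, Th0+Dopa 2, Th0 3 and Th0+Dopa 3 in turn, the limma adjusted p of Mcpt8 was 0.0258, 0.0697, 0.0444 and 0.0695.

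Il4 and Il13, the defining cytokines of Th2 cells, rose. Il4 (ENSMUSG00000000869, chromosome 11, 53602982 to 53618669, GRCm38) went from 87.0 ± 2.13 to 240.4 ± 30.4 FPKM (SD, n = 2 per group, levels taken across the separate tables), a log2 difference of 1.45 ± 0.12 or 2.73-fold (limma adjusted p = 0.00298). Il13 (ENSMUSG00000020383, chromosome 11, 53631324 to 53634702), its neighbour, went from 60.9 ± 5.05 to 129 ± 10.9 FPKM, 1.07 ± 0.10 (adjusted p = 0.00447). Il5, in the same cytokine cluster (chromosome 11, 53720794 to 53725106), had 0.51 ± 0.17 (adjusted p = 0.126), and Gata3, the Th2 transcription factor, 0.12 ± 0.14 (adjusted p = 0.608), neither past the threshold. Gata3 had -0.060 after the GC and length correction. It had -0.12 with libraries scaled to a common sum and -0.048 with small RNA left out first, moving about as far as the median of all genes did. The Th2 list rose (median 0.39, camera adjusted p = 0.00240; adjusted p = 0.703 with an estimated correlation). Of its 21 tested genes 9 rose and 1 fell, 11 and 1 when adjusted over the list alone. Beside Il4 and Il13, the steroid synthesis enzyme Cyp11a1 rose by 1.52 ± 0.11, the transcription factor Maf by 1.20 ± 0.22 and the nuclear receptor Pparg by 1.05 ± 0.15. Gfi1, Nfil3, Crlf2 and Irf4 rose by 0.67 ± 0.11, 0.64, 0.77 ± 0.15 and 0.51. The gene that fell, Il1rl1 (-1.81 ± 0.33, adjusted p = 0.0288), encodes the IL-33 receptor, which mast cells and basophils also carry, and markers of those cells fell in the same libraries. After the GC and length correction the list's median was 0.30, and Gfi1, Crlf2 and Il1rl1 did not pass (0.40 ± 0.10, 0.14 ± 0.13 and -1.63 ± 0.34, adjusted p = 0.0878, 0.555 and 0.0595). For Il4, limma adjusted p was 0.0507 without the trend, and 0.129, 0.0896, 0.193 and 0.0706 without Th0 2, Th0+Dopa 2, Th0 3 and Th0+Dopa 3 in turn, with log2 differences from 1.30 to 1.60. For Il13 these values were 0.0616 and 0.141, 0.165, 0.266 and 0.108.

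**Figure D2:**
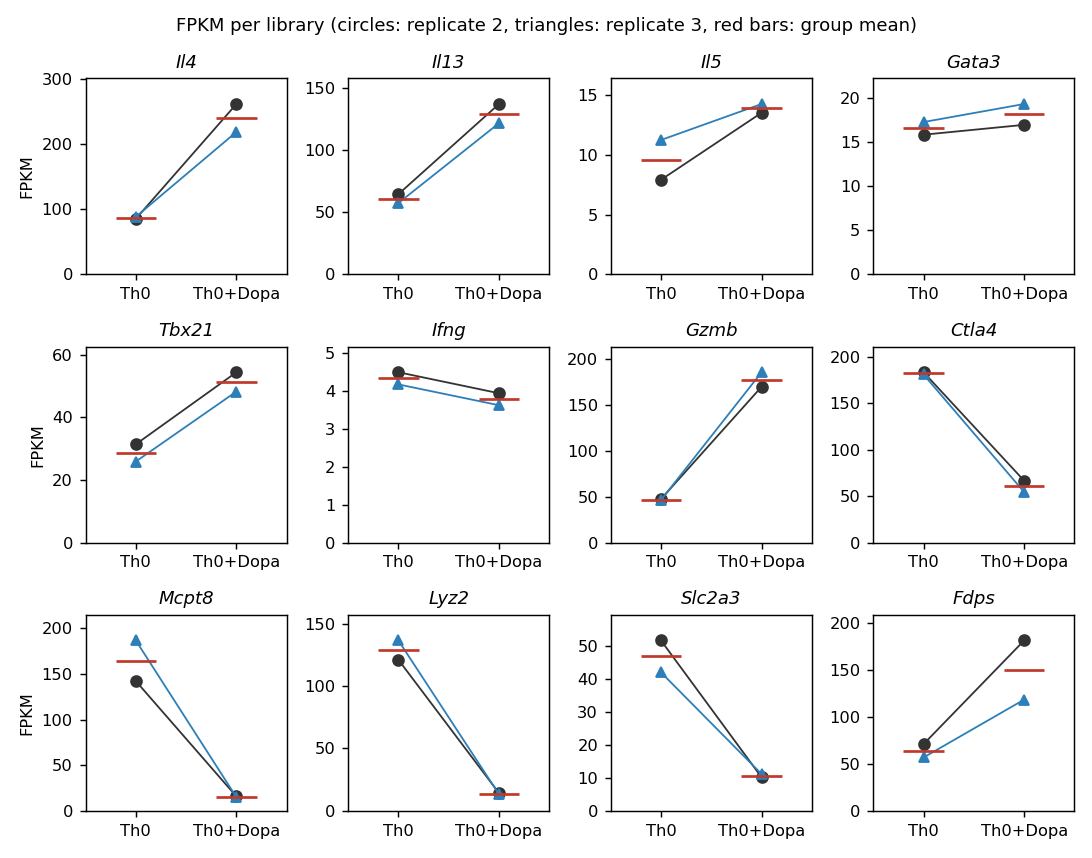
FPKM per library (y axis, linear, from 0) of 12 genes in Th0 and Th0+Dopa (x axis). Circles are replicate 2, triangles replicate 3, lines join libraries of a table and red bars are group means. Il4 rose from 85.5 and 88.5 to 262 and 219.

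Genes of other T helper programs moved in several directions, and no other list of these programs passed camera. Tbx21, the Th1 transcription factor, rose by 0.82 ± 0.12 (limma adjusted p = 0.0140), but did not pass with libraries scaled to a common sum (0.58, adjusted p = 0.0570). Ifng had -0.16 ± 0.22 (adjusted p = 0.684). Of 14 tested Th1 genes (median 0.36, camera adjusted p = 0.103), 4 rose: Tbx21, the chemokine Ccl4 (2.03 ± 0.13), Il12rb1 (1.09 ± 0.11) and Ly6c1 (2.04 ± 0.14), a near copy of Ly6c2 and so uncertain. By fry, which tests whether a list's genes move one way on balance, the Th1 list was the only list that passed (adjusted p = 0.0177). Foxp3, the factor of regulatory T cells, lay under the filter, at most 0.701 FPKM. Regulatory T cell genes (median -0.18, camera adjusted p = 0.0804) included 2 calls of 13, Ctla4 (-1.58 ± 0.12) and Tnfrsf9 (-1.27 ± 0.11). Follicular helper genes (median -0.11, camera adjusted p = 0.118) included 3 of 10, the costimulator Icos (-1.32 ± 0.11), Btla (-1.02 ± 0.12) and Cd200 (-1.03 ± 0.15), all lower. Of 6 tested Th17 genes (median -0.37, camera adjusted p = 0.165), Ahr fell by 1.75. Inhibitory receptor genes (median -0.02, camera adjusted p = 0.586) split between Ctla4 and Btla, which fell, and Havcr2, which rose by 1.70 ± 0.26. Gzmb, a cytotoxic protease, rose by 1.90 ± 0.11 (adjusted p = 0.000952), the only call of 9 in the cytotoxic granule list (median 0.29, camera adjusted p = 0.118). Myeloid cell markers were lower in the same libraries (macrophage list median -1.92). Leaving out Th0 2, Th0+Dopa 2, Th0 3 or Th0+Dopa 3 gave Ctla4 adjusted p values of 0.126, 0.0758, 0.175 and 0.0791.

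Naive and memory T cell genes fell as a list (median -0.47, camera adjusted p = 0.000285; adjusted p = 0.703 with an estimated correlation). Of 15 tested, 4 fell and 1 rose, 7 and 1 when adjusted over the list alone. Igfbp4 changed by -2.08 ± 0.20, the homing receptor Ccr7 by -0.70 ± 0.11 and S1pr1 by -0.73 ± 0.16, while Il7r rose by 0.93 ± 0.15. S1pr1 did not pass after the GC and length correction (-0.64 ± 0.16, adjusted p = 0.0843). The list of targets of the p53 tumour suppressor fell (median -0.27, camera adjusted p = 0.00240; adjusted p = 0.703 with an estimated correlation), with 5 of 20 lower and 1 higher, 6 and 2 adjusted over the list alone. Ei24, Plk2, Mdm2 and Pmaip1 had -1.01 ± 0.13, -1.01 ± 0.13, -0.73 ± 0.11 and -0.87 ± 0.15, and Sesn1 rose by 0.88 ± 0.16. Pmaip1 did not pass after the correction (-0.66 ± 0.14, adjusted p = 0.0587). IL-2 and STAT5 response genes did not pass as a list (median 0.04, camera adjusted p = 0.479). Its members Gzmb, Tnfrsf8 (1.69), Socs1 (1.26 ± 0.18) and Pim1 (0.63) rose, Il2 (-0.93 ± 0.10) and the survival factor Bcl2 (-0.68 ± 0.15) fell, and Il2ra had 0.24 ± 0.13 (adjusted p = 0.269), or -0.0079 with libraries scaled to a common sum. Socs1 and Bcl2 did not pass after the correction (1.03 ± 0.20 and -0.63 ± 0.13, adjusted p = 0.0506 and 0.0588). T cell receptor and immediate early genes had a median of 0.000919 and a camera adjusted p of 0.955, with 5 of 24 higher and 3 lower. Junb rose by 1.39 ± 0.11 (0.90 ± 0.08 after the correction), and Nr4a2 and Tnfrsf9 fell by 1.45 and 1.27. Markers of myeloid cells fell in the same libraries, with a median of -1.92 for the macrophage list.

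The glycolysis list fell (median -0.67, camera adjusted p = 6.72e-12; adjusted p = 0.703 with an estimated correlation). Of 21 tested members 14 fell, 18 when adjusted over the list alone, and none rose by either count. The glucose transporter Slc2a3 changed by -2.03 ± 0.15 (limma adjusted p = 0.00229), the lactate exporter Slc16a3 by -1.05 ± 0.12, the regulator Pfkfb3 by -1.27 ± 0.19 and Bnip3 by -1.83 ± 0.13. The hypoxia list, which shares Bnip3, Pdk1 and Slc2a1 with it, also fell (median -0.84, camera adjusted p = 1.28e-11; adjusted p = 0.703 with an estimated correlation): 12 of 16 were called lower, 14 adjusted over the list alone. The mitophagy receptor Bnip3l had -1.74 ± 0.11, the adenylate kinase Ak4 -1.52 ± 0.22 and Ankrd37 -1.39 ± 0.19. After the GC and length correction, the medians of the glycolysis and hypoxia lists were -0.76 and -0.83. Markers of myeloid cells fell in the same libraries (median -1.92 for the macrophage list and -3.22 for the granulocyte list). The adjusted p of Slc2a3 was 0.0805, 0.112, 0.0882 and 0.0955 without Th0 2, Th0+Dopa 2, Th0 3 and Th0+Dopa 3.

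Sterol synthesis genes rose (median 0.62, camera adjusted p = 3.65e-09; adjusted p = 0.703 with an estimated correlation). In all, 9 of 24 rose and 0 fell, and 21 rose when adjusted over the list alone. The farnesyl diphosphate synthase Fdps rose by 1.19 ± 0.12, Mvd by 1.00 ± 0.17, the squalene synthase Fdft1 by 0.84 ± 0.13 and the regulator Srebf2 by 0.91 ± 0.16. Mvd and Srebf2 did not pass after the GC and length correction (0.73 ± 0.16 and 0.72 ± 0.15, adjusted p = 0.0656 and 0.0617). Amino acid and integrated stress response genes rose as well (median 0.50, camera adjusted p = 3.13e-06; adjusted p = 0.703 with an estimated correlation), 13 of 25 higher and 1 lower, 15 and 1 adjusted over the list alone. They included Trib3 (1.57 ± 0.19), the glutathione-degrading enzyme Chac1 (1.53 ± 0.20), the asparagine synthetase Asns (1.18 ± 0.10), the transcription factor Atf4 (0.69) and Cebpb (1.76 ± 0.27), the last not past the threshold after the correction (1.04 ± 0.24, adjusted p = 0.0723). Vldlr was the member that fell (-1.16 ± 0.24), and it did not pass after the correction (-1.14 ± 0.24, adjusted p = 0.0588). Nuclear genes of oxidative phosphorylation rose by a smaller amount (median 0.40, camera adjusted p = 6.29e-06; adjusted p = 0.831 with an estimated correlation): 12 of 30 rose and 0 fell, 19 and 2 adjusted over the list alone, among them Cyc1 (0.92 ± 0.11, or 0.51 ± 0.09 after the correction), Uqcrc1 (0.73 ± 0.11), Ndufa2 (0.74 ± 0.11) and Sdhb (0.65 ± 0.10). Their median was 0.34 after the correction. Transcripts encoded by the mitochondrial genome went the other way: 8 of 12 tested fell and 0 rose, with a median of -1.22, a group chosen after its values were seen (camera adjusted p = 3.83e-09, or adjusted p = 0.202 with an estimated correlation). Their median was -0.96 after the correction, with 6 called lower and 0 higher. Mitochondrial ribosomal RNA, which the kit depletes, was lower as well: mt-Rnr1 stood at 4826 and 8208 FPKM in Th0 and 565 and 2809 with dopamine. A difference between the libraries in their making was therefore not told apart from fewer mitochondrial transcripts in the cells. These 3 lists of nuclear genes rose in libraries where the macrophage list had a median of -1.92. Asns had adjusted p values of 0.129, 0.112, 0.193 and 0.0900, and Fdps of 0.206, 0.239, 0.430 and 0.115, without Th0 2, Th0+Dopa 2, Th0 3 and Th0+Dopa 3.

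**Figure D3:**
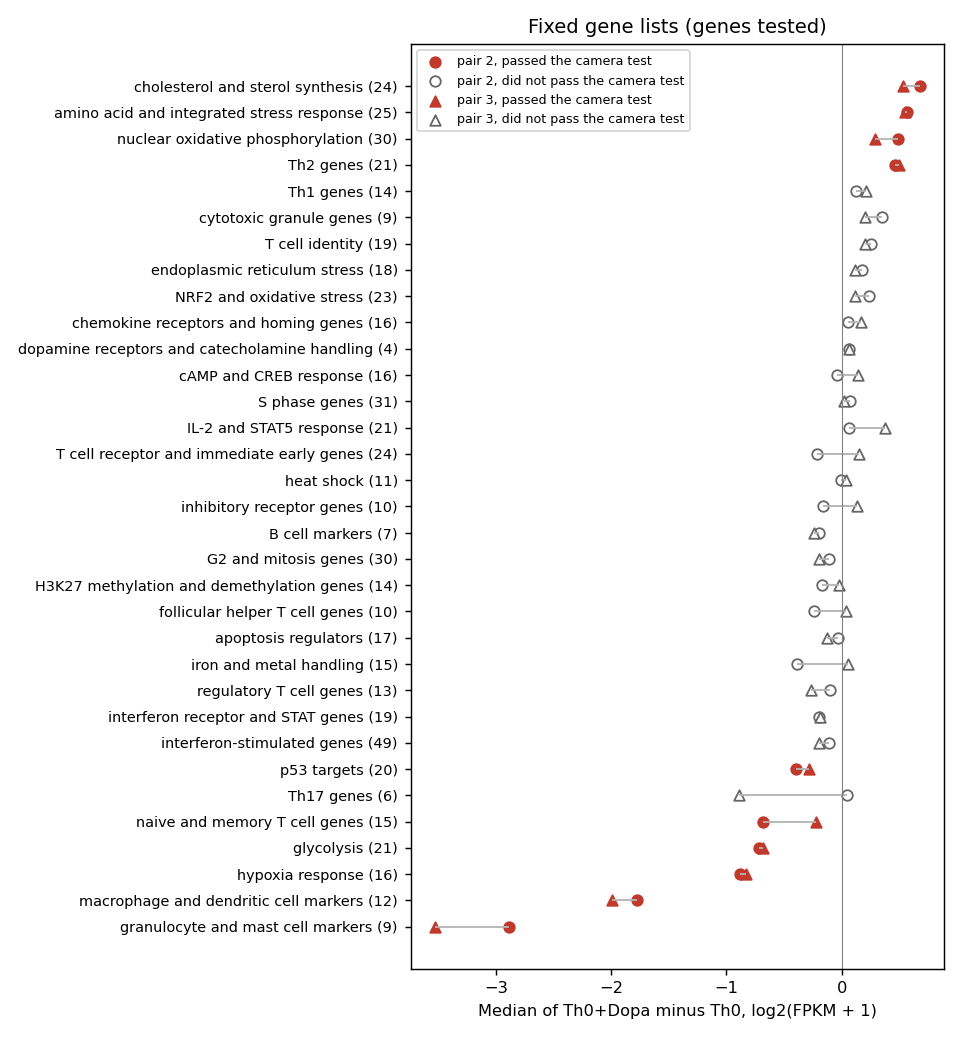
Median log2(FPKM + 1) difference, Th0+Dopa minus Th0 (x axis), of the 33 tested lists (y axis, number of tested genes in parentheses) in pair 2 (circles) and pair 3 (triangles). Filled red symbols mark the 10 lists that passed camera at the preset correlation, 4 higher and 6 lower.

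Of the genes for receiving or handling dopamine, few were measurable. Drd4 (chromosome 7, 141292006 to 141296464) and Drd2 were listed at 0 in all 4 libraries, and Drd1, Drd3 and Drd5 reached at most 0.0438, 0.147 and 0.0729 FPKM, less than the value of 1 fragment on a 1 kb transcript in the library concerned. Of the 4 members of the catecholamine list that were tested (median 0.07, camera adjusted p = 0.926), the vesicular monoamine transporter Slc18a2, also a mast cell and basophil gene, fell (-1.29 ± 0.29, adjusted p = 0.0481), but did not pass after the correction (-1.18 ± 0.30, adjusted p = 0.0901). Stat2, a mediator of interferon signalling, had -0.22 ± 0.19 (limma adjusted p = 0.510; 95% interval -0.70 to 0.26). Interferon receptor and STAT genes did not pass as a list (median -0.19, camera adjusted p = 0.118), though Stat3 fell (-1.15 ± 0.11) and Socs1 rose. Interferon-stimulated genes did not pass either (median -0.21, camera adjusted p = 0.269): of 49 tested, Ly6a (1.39), Bst2 (0.85 ± 0.14), Igtp (0.55), Irgm1 (0.53) and Gbp4 (0.50) rose and Slfn1 (-0.70 ± 0.12) and Zbp1 (-0.61) fell. Bst2 and Slfn1 did not pass after the correction (0.50 ± 0.11 and -0.58 ± 0.11, adjusted p = 0.0713 and 0.0506). Rtp4 had -1.34 ± 0.32 (adjusted p = 0.0559). In the H3K27 methylation list (median -0.10, camera adjusted p = 0.135), the methyltransferase Ezh2 was the only call of 14 (-0.47 ± 0.10, adjusted p = 0.0424) and did not pass after the correction (-0.34 ± 0.08, adjusted p = 0.0861).

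Cell cycle lists did not pass. Of 31 S phase genes (median 0.06, camera adjusted p = 0.741), Cdt1 (1.01 ± 0.18) and Tk1 (0.55 ± 0.11) rose and Ccne2 (-0.96 ± 0.20) fell. None of these 3 passed after the GC and length correction (0.73 ± 0.17, 0.39 ± 0.10 and -0.79 ± 0.19, adjusted p = 0.0780, 0.0815 and 0.0812). Of 30 genes of G2 and mitosis (median -0.10, camera adjusted p = 0.118), Mki67, a marker of proliferating cells, was the only call (-0.71 ± 0.12). Iron and metal handling genes (median -0.17, camera adjusted p = 0.145) had 5 of 15 lower, among them the metallothionein Mt1 (-0.87) and the ferritin chain Fth1 (-0.54), and 2 higher, Mt3 (1.795 ± 0.32) and Ftl1 (0.54 ± 0.11), neither past the threshold after the correction (1.37 ± 0.30 and 0.23 ± 0.08, adjusted p = 0.0645 and 0.147). Chemokine receptor and homing genes (median 0.08, camera adjusted p = 0.622) had a mean of -0.14, opposite in sign to the median, and the test's direction followed the mean. Its 5 calls of 16 were lower: Ccr1 (-1.997 ± 0.24), Ccr2 (-1.26 ± 0.26), Cxcr4, Ccr7 and S1pr1. Ccr1 and Ccr2 are also receptors of myeloid cells, and Ccr2 did not pass after the correction (-1.03 ± 0.24, adjusted p = 0.0767). The cAMP and CREB list (median 0.07, camera adjusted p = 0.741) likewise had a mean of -0.10, with Crem (-0.94 ± 0.13) and Nr4a2 lower among 16. Lists of apoptosis regulators (median -0.13, camera adjusted p = 0.779), heat shock (median -0.00400, camera adjusted p = 0.590), endoplasmic reticulum stress (median 0.12, camera adjusted p = 0.487) and NRF2 targets (median 0.11, camera adjusted p = 0.575) did not pass. The apoptosis and heat shock means, 0.00842 and 0.00436, had signs opposite to the medians, as did the catecholamine list's mean of -0.17. Of 18 tested endoplasmic reticulum stress genes, 4 were called higher and 1 lower, and of 23 NRF2 targets 3 and 1. Of 11 heat shock genes, 0 were called higher and 1 lower, and of 17 apoptosis regulators 2 and 1. The chaperone gene Pdia6 rose by 0.61 ± 0.10 and the thioredoxin Txn1 by 0.71 ± 0.10. Dnaja1 fell (-0.51 ± 0.11), a call that the correction ended (-0.36 ± 0.10, limma adjusted p = 0.107).

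The differences followed the GC content of the transcripts. Their median was -0.21 for genes under 40% GC and 0.49 for genes over 60%, with Spearman's rho across genes of 0.315 in pair 2 and 0.316 in pair 3. Libraries of the same group also differed along GC: rho was 0.258 for Th0 2 minus Th0 3 and 0.251 for Th0+Dopa 2 minus Th0+Dopa 3. Genes with transcripts of up to 300 nt had medians of 0.51 in pair 2 and 0.64 in pair 3 (1.13 for the mean of the pairs), and rho with length was -0.241 and -0.0807. After the correction for both properties, limma called 430 genes higher and 394 lower, 730 of them shared with the calls as deposited and all 730 with the same sign. Of 90 named calls with GC and length values, 75 passed after the correction and 15 did not. Over these 15, all with the same sign as before, the corrected difference was a median of 0.761 times the deposited one (0.373 to 0.934), and the SE 0.928 times (0.848 to 1.12). The ratio of difference to SE fell for all but Bcl2, whose call ended through the prior or the adjustment over all genes.

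**Figure D4:**
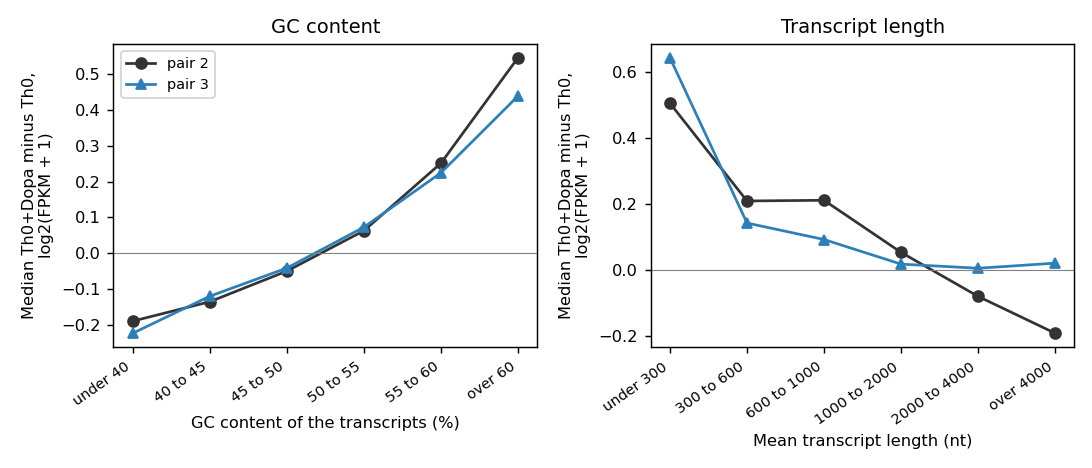
Median log2(FPKM + 1) difference, Th0+Dopa minus Th0 (y axis), of tested genes grouped by GC content (left, x axis in percent) and mean transcript length (right, x axis in nt), for pair 2 (circles) and pair 3 (triangles). Medians rise from -0.19 and -0.22 under 40% GC to 0.55 and 0.44 over 60%.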

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

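With 1 residual degree of freedom per gene, the count of calls leans on the prior fitted over all genes. Counts of higher and lower genes were 717 and 501 as reported. They were 442 and 298 with no filter on low values, 429 and 282 with the median of ratios within each table, 106 and 150 without the trend, and 430 and 394 after the GC and length correction with the replicate block, a setting chosen after the data were seen. Each library scaled to a common sum gave 380 and 1082, and 433 and 927 with small RNA genes left out first. With no replicate block, which also takes out the table, they were 256 and 240, all 496 shared with the reported calls. Deviations of same-numbered libraries from their group means correlated at 0.0869 across genes. A shared table would raise this value too, so it gives the block little backing. The block rests only on the tables having been made separately. Leaving out 1 library gave 2 to 20 higher and 1 to 23 lower genes, in fits without the block where the lone library was assumed to vary like the others. In these fits 9 (without Th0 2), 0 (without Th0+Dopa 2), 4 (without Th0 3) and 1 (without Th0+Dopa 3) of the 94 named calls passed. These fits hold fewer libraries, have no block and use libraries scaled by the median of ratios over all 4. Beyond this, the cause was not tested. Genes at least 2-fold apart in both pairs numbered 519 as reported, 245 with a pseudocount of 5, which shrinks low genes by construction, and 327 with a mean FPKM of at least 5, where fewer genes are tested. The correlation of the pairs, 0.536, was 0.429 and 0.637 with pseudocounts of 0.1 and 5, 0.472 with no filter, 0.597 at a mean of at least 5, 0.510 with libraries scaled to a common sum, 0.503 with small RNA left out first and 0.492 after the GC and length correction. Of 33 lists, 10 passed as reported. By camera with an estimated correlation, which uses the 1 residual degree of freedom, 0 passed (0 at an unadjusted p under 0.05). By fry only 1 passed, the Th1 list, which camera had not called, so 0 of the 10 kept their call there (fry adjusted p = 0.0950 to 0.237). In both pairs, 12 lists lay outside the central 95% of random lists. The 10 lists kept their call and direction in every other refit that tested them, the single-library omissions included (10 to 13 lists called). At a mean FPKM of at least 5 the macrophage list had fewer than 4 genes and no value. Gata3 reversed to -0.12 and -0.048 under these scalings and to -0.060 under the GC and length correction, and Il2ra to -0.0079 with libraries scaled to a common sum. Neither was called. The scalings moved the median of all genes from 0.03 to -0.21 and -0.14, about as far as these genes. Of the 94 named calls, 40 passed without the trend, 68 with no block, 81 with libraries scaled to a common sum, 79 with the median of ratios and all 94 with a pseudocount of 0.1 or robust eBayes; none reversed. Each pair alone gives values with no test. No gene of the naming rule changed sign there, but the rule takes calls and list members only with the same sign in both pairs. Only the genes chosen in advance could have changed sign. Cst3, named beyond the rule, was 0.37 in pair 2 and -0.41 in pair 3. Th0 3 was the shallowest library by the value of 1 fragment, an uncertain estimate, so values near 1 FPKM may be least certain there.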

Other observations

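The tests of explanations in this part, the histone, small RNA and basophil groups and the genes of its first 2 paragraphs were chosen after the results were seen, and Il4, Il13, the fixed lists and the planned refits before. Penk, the precursor of enkephalins, fell from 109 and 133 FPKM in Th0 to 13.3 and 15.8 with dopamine (-2.97 ± 0.11, limma adjusted p = 0.000396). Ccl22, Ccl24 and Ccl17, chemokines often made by macrophages and dendritic cells, fell by 2.45, 2.22 and 1.61. The cytokine Csf2 rose from 8.14 and 8.49 FPKM to 20.8 and 22.6 (1.29 ± 0.15, adjusted p = 0.00741). Il6 fell (-1.26 ± 0.26, adjusted p = 0.0388), and did not pass after the GC and length correction (-1.01 ± 0.24, adjusted p = 0.0797). Abcg1, a cholesterol exporter, and Fads2, a fatty acid desaturase, rose by 1.94 ± 0.16 and 1.67 ± 0.25. Txnip, an inhibitor of thioredoxin whose transcription follows glucose, fell (-1.80 ± 0.13).

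Rmrp and Rpph1, the RNA parts of the ribonucleases MRP and P, rose by 2.17 ± 0.21 and 1.94 ± 0.23 (limma adjusted p = 0.00475 and 0.00815; 1.28 ± 0.09 and 0.88 ± 0.08 after the GC and length correction), whereas Rn7sk, the most abundant of the small RNAs named here, had -0.15 ± 0.35 (adjusted p = 0.825). Mitochondrial ribosomal RNA, which the kit depletes, was lower: mt-Rnr1 fell by 2.32 and mt-Rnr2 fell by 1.81. The AT-rich satellite-like genes Gm10800 and Gm10801, near-identical copies of each other, changed by -3.45 ± 0.21 and -3.43 ± 0.19.

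Markers of granulocytes, mast cells and macrophages were lower in both libraries with dopamine. A GC and length bias as the whole cause is argued against by the median of the macrophage list after correction, -1.88, the higher of the 2 lists. Of 16 tested markers with a Th0 mean of at least 5 FPKM, 15 (93.75%) fell by more than 1 on the log2 scale, but these markers define the pattern, so this share cannot decide for or against fewer such cells. The most abundant of them, Mcpt8 and Lyz2, had Th0 means of 165 and 129 FPKM, and the labels name naive CD4+ T cells, a selection that should remove such cells. Open are fewer such cells through dopamine or unequal purity of the cultures, and lower transcripts within them.

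Histone cluster genes were higher in both libraries with dopamine. GC and length are argued against as the whole cause: over 20 coding genes matched to each, themselves at a median of 0.48, the median excess was 1.37 in pair 2 and 1.13 in pair 3, positive in both for 46 of 55. More cells in S phase as the whole cause is argued against by the S phase list, whose median was 0.057. Of its 31 tested genes, 15 were higher in both pairs and 7 lower in both, so a part is not excluded. Better capture of short or non-polyadenylated RNA may contribute, since snRNA, snoRNA and scaRNA genes had pair medians of 0.84 and 0.67. Of these 184 genes, however, only 85 were higher in both pairs and 10 were lower in both. Rn7sk, another small RNA, did not rise. A treatment effect on histone RNA, and reads shared between near-identical copies, stay open and were not tested.

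Il4 and Il13 were higher while other cell types' markers were lower. RNA from basophils or mast cells, which also make these cytokines, is argued against by the median of Mcpt8, Cpa3, Ms4a2 and Fcer1a, -2.80. A larger share of T cells is argued against as the whole cause by the T cell identity list, whose median was 0.23, and a GC and length bias by the smaller of the corrected differences, 0.99. A treatment effect in T cells is therefore a candidate explanation, as a hypothesis found and tested on the same 4 libraries, in which Il4 did not pass in any fit that left out 1 library (adjusted p from 0.000544 to 0.193 over all refits).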
